A study of Mus musculus with 18 samples.

How the data were processed

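RNA was measured by sequencing in 18 samples of sorted cells from mouse dorsal skin. The samples formed 6 groups of 3: control skin at day 0 and skin treated with DPCP at day 2, each sorted into populations labelled EpSCs, Germ and Bulge. Groups and replicate numbers from 1 to 3 came from the sample titles. The labels did not say whether samples of a group came from separate animals, nor whether same-numbered samples of different populations shared an animal, and if they did not come from separate animals the p-values measure only the spread between these samples.

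Per the labels' protocols, skin was digested with trypsin, cells were sorted by flow cytometry, and libraries were made with a stranded poly(A) RNA kit and sequenced as paired ends on a NovaSeq. Per the submitters' processing notes, the tools included FastQC 0.11.9, cutadapt 3.5, STAR 2.7.6a and limma 3.60.6, and the builds named were GRCm38 and mm10. The read counter, the annotation, the filter on low expression, the normalization and the limma model are not given in the sources used here.

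The data were a table of 48 columns and 13816 gene IDs, of which 13322 were protein-coding and 494 lincRNA, per the file headers and the type column. Of these columns, 36 held values per library (18 of TPM and 18 of scaled expression). Their column names matched no sample label, so they were not used, and no sample was assigned by order or value. The 9 columns used held the authors' comparisons of DPCP with control in each population. The authors deposited a log2 fold change (DPCP minus control) for each gene and comparison. The authors also deposited a p-value and an adjusted p-value for each. The deposited adjusted p equalled a Benjamini-Hochberg adjustment over all 13816 IDs, with a largest difference of 2.0e-14. No level, standard deviation, standard error or depth per sample could therefore be given: the depth is unknown, and the authors' p-value is the measure of error beside each fold change. A fold change has no stated floor or pseudocount, so the fold of a gene with low expression in either group cannot be bounded.

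A gene was called when the authors' adjusted p was under 0.05. The planned tests on values per library, and the comparisons between populations in control skin, were replaced or left out because the library columns were not used. The overlap of calls was set beside the number expected for independent calls. The 3 comparisons shared no libraries.

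Whether the DPCP effect differed between populations was tested by an approximation chosen after the content of the table had been seen. The p-value and sign of each log2 fold change were turned into a normal score, and the standard error was rebuilt as the fold change divided by that score. The difference of 2 fold changes was divided by its combined standard error, and p was adjusted by Benjamini-Hochberg over all genes. This assumes independent libraries and ignores how limma pools the spread. In simulated data of 13816 genes, the test made 37 calls for Germ against Bulge, 1 of them false, 70 for EpSCs against Bulge with 8 false, and 61 for EpSCs against Germ with 4 false. It recovered 44%, 72% and 54% of differences of 4 on the log2 scale, in that order, and 4%, 18% and 14% of differences of 2. The false share was above the threshold for a call in both comparisons with EpSCs, and below it for Germ against Bulge. The real data gave many more calls than the simulated data (828, 1433 and 1690, in the same order). The simulated false shares and recovery therefore need not hold for the real calls.

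30 gene lists were fixed before the data were examined: 3 of follicle and epidermal identity, 17 of cell programs, 1 of immediate early genes (which cell dissociation can induce) and 9 of other cell types. Each list was tested with limma 3.58.1 (cameraPR, 2-sided, preset inter-gene correlation of 0.01) on the normal scores, and p was adjusted over the 30 lists of a comparison. An estimated correlation needs values per library and could not be had, so 0.05 was tried in its place. In simulated scores, independent between genes, with lists drawn at random, the test called 3 of 3 lists shifted by 1.5 and 0 of the others. This simulation did not test lists whose genes vary together, as those of real programs can. Counts of called members are given over all genes and, in those words, adjusted over the list alone. Members were counted as gene IDs, and the symbols Aldoa and Ccl27a each had more than a single ID. 7 further lists were added later, for the closing section.

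Genes were named by a rule fixed beforehand: the 10 largest changes in each direction among called genes, skipping predicted symbols, up to 4 members of each list by adjusted p, the 5 largest called differences of effects in each direction, and always Cd34, Itga6, Ly6a, Cdh3, Lgr5, Krt15, Spp1, Cd44, Mki67 and Ptprc. Its conditions on a mean level of 10 and on groups that do not overlap needed values per library and could not be applied. Genes called in all 3 populations, and members of the 7 later lists, were named outside the rule, after their values were seen. Coordinates came from GENCODE M21 on GRCm38. Of the gene IDs, 13806 (99.9%) matched it once version suffixes were removed. Keratins, kallikreins, small proline-rich proteins, serpins and cytochromes P450 are families of similar genes, and how reads shared between members were counted is not known, so single members are uncertain.

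Alternatives changed the adjustment, the threshold, the minimum size of change, the genes adjusted over, the degrees of freedom of the difference test, and the statistic and correlation of the list test. Scripts used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9 and R 4.3.3.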

Results

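Bulk RNA was sequenced from cells sorted from the dorsal skin of mice. DPCP (diphenylcyclopropenone) is a contact sensitizer that provokes an allergic reaction in skin, and the series concerns hair growth and macrophages expressing SPP1 (osteopontin) in contact hypersensitivity. Control skin (day 0) and DPCP-treated skin (day 2) were each sorted into 3 populations labelled EpSCs, Germ and Bulge, with 3 samples in each of the 6 groups. The labels describe the cells as keratinocytes and the protocol as hair follicle stem cells, and EpSCs is not spelled out. In the field, the bulge is the stem cell niche of the follicle and the germ lies just below it. The fold changes and adjusted p-values of single genes below are those of the authors' deposited table, made with limma and adjusted by Benjamini-Hochberg over 13816 genes. Values per sample were not used here, so no standard deviation accompanies them, and sequencing depth is unknown.

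The comparison of DPCP with control in each population asked which genes differed in the RNA of the sorted cells. Such a difference can come from a change within cells or in which cells were sorted, and these were not told apart. Every control was taken at day 0 and every DPCP sample at day 2, so an effect of DPCP cannot be separated from one of the day or of when samples were collected and sorted, and "DPCP effect" stands for the sum of these. In the authors' deposited table, 5516 genes changed in EpSCs (2748 higher and 2768 lower, 39.9% of those tested). The same table called 1421 genes in Bulge (708 higher and 713 lower, 10.3%) and 146 in Germ (117 higher and 29 lower, 1.06%). At an unadjusted p under 0.05 the authors' deposited table held 6760 genes in EpSCs, 4037 in Bulge and 3545 in Germ. The median log2 fold change over all genes was −0.0034 in EpSCs, −0.02 in Bulge and 0.10 in Germ.

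**Figure D1:**
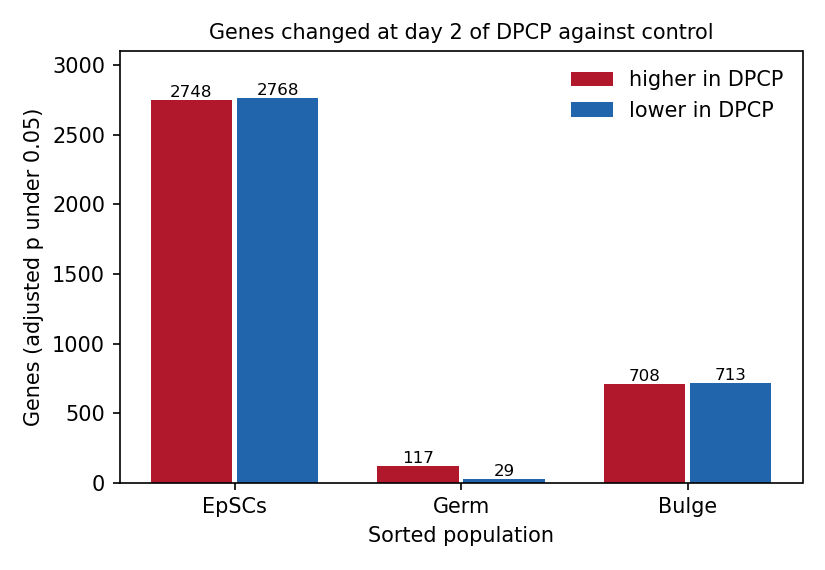
Number of genes (vertical axis) with an adjusted p under 0.05 in the authors' deposited table, by sorted population (horizontal axis), higher (red) or lower (blue) at day 2 of DPCP than in control. EpSCs and Bulge had nearly equal numbers in each direction, while Germ had 117 higher and 29 lower.

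EpSCs from DPCP skin had higher expression of stress keratins and alarmins, interferon response genes, antigen presentation genes and cholesterol synthesis genes. They had lower expression of hemidesmosome and basement membrane genes and of immediate early genes. Ribosomal protein genes and mitochondrially encoded genes, lists added after the data were seen, were lower in EpSCs too (medians −1.27 and −2.55, list test adjusted p = 6.26e-23 and 4.04e-06). The largest increase in the authors' deposited table was that of Igfl3, an IGF-like family member, at a log2 fold change of 9.40 (673-fold, adjusted p = 2.67e-06). Lrat, which esterifies retinol, followed at 8.63, Ear2, a ribonuclease of the eosinophil-associated family, at 8.22, Serpinb3a at 7.43, the iron-chelating protein gene Lcn2 at 7.25 and the protease gene Klk6 at 7.03 in the authors' deposited table. Eya2 (6.21), Pglyrp3 (6.13), Gsdmc (6.07) and the keratin gene Krt79 (6.04) completed the 10 largest increases there. Krt79 was 1 of 3 genes, Krt17 among them, that had the smallest adjusted p in EpSCs in the authors' deposited table, 1.28e-07. The largest decreases in the authors' deposited table were those of Nlgn3, a synaptic adhesion gene, at −8.16 (adjusted p = 8.49e-05), Greb1 at −7.84, Usp29 at −7.76, Slc4a10 at −7.67 and Foxp2 at −7.43. Stra6l (−7.38), Ank1 (−7.22), Col5a3 (−6.76), Myrf (−6.63) and Prrx1 (−6.58) followed in the same table.

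Of the 22 stress keratins and alarmins, 17 rose and 2 fell in EpSCs, with the same numbers adjusted over the list alone (median log2 fold change 2.41, list test adjusted p = 4.93e-05). Krt6a, a keratin induced in wounded and hyperproliferative epidermis, rose 25.2-fold (4.66, adjusted p = 2.47e-06) in the authors' deposited table. Krt17 rose by 4.13 (adjusted p = 1.28e-07) and the cornified envelope precursor Sprr1a by 2.80 in that table, while Ptgs2, the inducible cyclooxygenase, fell by 3.23 (adjusted p = 0.000147). Of 26 interferon response genes, 15 rose and 2 fell (18 and 2 adjusted over the list alone, median 1.64, adjusted p = 0.000166). The authors' deposited table had Cxcl9, a chemokine for T cells, at 3.58, Ifi47 at 3.04 and Gbp2 at 1.79, and Usp18, a negative regulator of interferon signalling, at −3.19. Of 20 antigen presentation genes, 12 rose and 0 fell (14 adjusted over the list alone, median 0.72, adjusted p = 0.000218). Among them, Cd74, the class II invariant chain, rose by 1.92 (adjusted p = 0.000147) and H2-Ab1 by 1.78 in the authors' deposited table. Ptprc, the pan-leukocyte marker CD45, fell by 3.65 there (adjusted p = 0.00176), and the lists of T cell, macrophage and Langerhans cell markers had medians of −0.76, −0.83 and −1.32 and were not called (adjusted p = 0.362, 0.615 and 0.33). The 4 neutrophil markers measured were not called as a list either (median 2.41, adjusted p = 0.33), with Cxcr2 (3.65), S100a9 (2.56) and S100a8 (2.26) higher and Mmp8 (−3.10) lower in the authors' deposited table.

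Of 18 cholesterol synthesis genes, 9 rose and 0 fell in EpSCs, both over all genes and adjusted over the list alone (median 0.65, adjusted p = 0.000774). The authors' deposited table had the sterol demethylase gene Cyp51 at 1.88 (3.67-fold, adjusted p = 5.12e-05), Sqle at 1.68 and Msmo1 at 1.67. Sebaceous gland markers, of cells that also make lipids, had 5 of 10 higher and 1 lower in EpSCs, over all genes and adjusted over the list alone, and were not called (median 1.38, adjusted p = 0.11, or 0.0107 with the fold change as statistic). Melanocyte markers had 2 of 8 higher and 0 lower, over all genes and adjusted over the list alone, and were not called either (median 2.22, adjusted p = 0.127, or 0.00102 with the fold change as statistic). Cornified envelope genes were called as a list, with 6 of 12 higher and 1 lower (7 and 1 adjusted over the list alone, median 1.83, adjusted p = 0.0253). Klk7 (5.10), Tgm1 (4.85) and Ivl (3.75) rose in the authors' deposited table. That list's adjusted p was 0.0848 at an inter-gene correlation of 0.05 and 0.0853 with ranks.

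Of 13 hemidesmosome and basement membrane genes, 11 fell and 0 rose in EpSCs (12 lower adjusted over the list alone, median −1.25, adjusted p = 6.15e-05). Itgb4 fell 3.85-fold (−1.94, adjusted p = 0.000339), the collagen XVII gene Col17a1 by 1.72 and the plectin gene Plec by 1.58 in the authors' deposited table. The largest falls of the list there were those of the collagen IV genes Col4a2 (−2.78) and Col4a1 (−2.33), which fibroblasts and endothelial cells also express. Of 6 fibroblast markers, 4 fell in EpSCs, with the same number adjusted over the list alone (median −2.30, adjusted p = 0.192, or 0.0238 with the fold change as statistic). Endothelial markers did not fall in EpSCs. Of 8, 0 were called over all genes or adjusted over the list alone (median 1.02, list test adjusted p = 0.33, or 0.0378 with the fold change as statistic). Of 16 immediate early genes, which tissue dissociation also induces, 13 fell and 2 rose (the same adjusted over the list alone, median −1.77, adjusted p = 7.48e-05). Atf3 was at −4.46, Fosb at −3.49, Ier2 at −2.01 and Jund at −1.75 in the authors' deposited table.

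Bulge stem cell markers moved both ways in EpSCs and were not called as a list (10 of 20 higher and 5 lower, 10 and 6 adjusted over the list alone, median 1.24, adjusted p = 0.145). In the authors' deposited table Cd200 rose 33.7-fold (5.08, adjusted p = 2.5e-07), Foxc1 by 3.95, Sox9 by 2.68, Lgr5 by 2.02 and Postn by 1.47, while Krt15 fell by 1.71 and Npnt by 2.02. With the fold change as the list statistic, adjusted p was 0.0108. Hair germ and early anagen genes had 4 members higher and 9 lower of 15 (the same adjusted over the list alone, median −1.32, adjusted p = 0.183). Bmp4 fell by 2.82, Wnt10a by 1.87 and Ccnd1 by 1.32 in the authors' deposited table, and Runx1 rose by 2.52. Interfollicular and upper follicle markers had 6 of 14 higher and 5 lower (7 and 5 adjusted over the list alone, adjusted p = 0.33), with Krt79 and Cst6 (5.18) up and Mt4 (−3.54) down in the authors' deposited table. Wnt targets had 1 higher and 5 lower of 13 (1 and 6 adjusted over the list alone, median −0.68, adjusted p = 0.113). Mitosis genes (4 higher and 5 lower of 24, the same adjusted over the list alone) and G1/S genes (1 higher and 7 lower of 24, 0 and 7 adjusted over the list alone) were not called either, at adjusted p = 0.539 and 0.127. The EpSCs count of called genes was 2590 with Benjamini-Yekutieli adjustment and 1161 when tested against a fold change of 1.5.

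In Germ, the genes that rose at day 2 of DPCP included melanocyte genes, and the list tests also called interferon response, mitosis, endothelial, fibroblast, migration and stress genes higher and interfollicular markers lower. The largest increases in the authors' deposited table were those of the complement gene C4b at 8.93 (adjusted p = 0.0232), Serpina3n at 8.79, the tyrosinase gene Tyr (363-fold), Enpp2, which makes lysophosphatidic acid (338-fold), and B4galt5 at 8.35. Tyrp1 (7.57), Trf (7.18), Timp1 (7.02), the endothelin receptor gene Ednrb (6.95) and the urea transporter gene Slc14a1 (6.86) followed in that table. The largest decreases in the authors' deposited table were those of Stra6, a receptor for retinol-binding protein, at −4.53 (adjusted p = 0.0232), the suprabasal keratin gene Krt1 at −3.22, Tmod4 at −3.07 and Cyp3a13 at −2.88. Cpxm2 (−2.38), the skin chemokine gene Ccl27a (−2.38), Akr1c19 (−2.36), Ackr4 (−2.23), Cbs (−1.93) and Gstm1 (−1.82) also fell in the authors' deposited table. A further gene ID with the symbol Ccl27a stood at −2.96 there and was not called (adjusted p = 0.12).

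Of 8 melanocyte markers, 6 rose in Germ over all genes and 8 adjusted over the list alone (median 6.09, list test adjusted p = 1.79e-08). Tyrp1, a pigment synthesis enzyme, rose 190-fold (7.57, adjusted p = 0.0081) in the authors' deposited table. Dct was at 6.45 (adjusted p = 0.0081), Sox10 at 6.26, Pmel at 5.28 and Mlana at 5.01 there. Of 8 endothelial markers, 2 rose (7 adjusted over the list alone, median 4.37, adjusted p = 0.000306), namely Kdr at 5.21 and Tie1 at 4.67 in the authors' deposited table. None of 6 fibroblast markers was called over all genes and 3 rose adjusted over the list alone (median 3.12, adjusted p = 0.0147). Dermal papilla markers, of which 4 were measured, had 1 member higher, Prdm1 (2.09 in the authors' deposited table), and 3 adjusted over the list alone (median 2.08, adjusted p = 0.0313, or 0.0629 with ranks). Prdm1 is also expressed outside the papilla, including in epidermal cells.

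In the same Germ comparison, 1 of 26 interferon response genes rose over all genes and 15 adjusted over the list alone (median 2.06, adjusted p = 2.09e-07). The called gene was Irgm1, at 1.96 (adjusted p = 0.0432) in the authors' deposited table, where Iigp1 stood at 5.07 (adjusted p = 0.061) and Gbp2 at 2.98 (adjusted p = 0.0572). Of 24 mitosis genes, 1 rose over all genes and 12 adjusted over the list alone (median 1.05, adjusted p = 5.41e-06). Ccnb2, a mitotic cyclin, was the called gene at 1.72 (adjusted p = 0.0368), with Cenpa at 1.18 (adjusted p = 0.0527) and Mki67 at 1.63 (adjusted p = 0.0832) in the authors' deposited table. Stress keratins and alarmins had 2 of 22 higher, Krt6a (3.64) and Lcn2 (2.28) in the authors' deposited table, and 4 adjusted over the list alone (median 2.41, adjusted p = 0.00806). Cholesterol synthesis genes had 1 of 18 higher, Sc5d (2.82-fold in the authors' deposited table), and 6 adjusted over the list alone (median 0.62, adjusted p = 0.00806, or 0.409 with the fold change as statistic).

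Migration and matrix genes had 1 of 16 higher in Germ, the actin-bundling gene Fscn1 (4.25, adjusted p = 0.0081 in the authors' deposited table), and 6 adjusted over the list alone (median 1.89, adjusted p = 0.0112). Of 10 osteopontin receptor genes, 1 rose, the integrin gene Itga9 at 4.30 (adjusted p = 0.0424) in the authors' deposited table, and 2 adjusted over the list alone (median 0.96, adjusted p = 0.0121). Endothelial, fibroblast and melanocyte markers rose in the same comparison (medians 4.37, 3.12 and 6.09). Which cells gave the rises of the migration and osteopontin receptor lists was not tested. BMP target and quiescence genes had 0 members called over all genes, and 5 higher and 1 lower adjusted over the list alone (median 0.61, adjusted p = 0.0147). That call was lost at a correlation of 0.05 (adjusted p = 0.0603) and with the fold change as statistic (0.258). Interfollicular and upper follicle markers were lower, with 1 of 14 called (Krt1) and 3 adjusted over the list alone (median −1.06, adjusted p = 0.000141). Bulge and hair germ markers were not called in Germ (medians 0.74 and 0.91, adjusted p = 0.109 and 0.0668), with 1 higher and 1 lower of 20, and 1 higher of 15, adjusted over the list alone. Ribosomal protein genes and mitochondrially encoded genes, lists added after the data were seen, were lower in Germ (medians −1.98 and −2.42, adjusted p = 2.04e-28 and 7.28e-06). With Benjamini-Yekutieli adjustment in place of Benjamini-Hochberg on limma's p-values, the Germ count of called genes was 0, beside 3545 genes at an unadjusted p under 0.05. At an adjusted p under 0.10 it was 923.

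In Bulge at day 2 of DPCP, stress keratins and alarmins, cholesterol synthesis genes and EGF family ligands were higher than in control, and sebaceous gland markers were lower. The largest increase in the authors' deposited table was that of the protease gene Klk6, at 11.19 (adjusted p = 0.0033). Slpi, a secreted protease inhibitor, stood at 10.29 (adjusted p = 0.042), Krt6b at 9.31, Sprr2h at 9.01 and the calprotectin genes S100a8 and S100a9 at 8.93 and 8.74 in the authors' deposited table. Lrat (8.76), Nppb (8.69), the defensin gene Defb14 (8.69) and Sprr1b (8.51) were the others of the 10 largest there. Several of the 10 largest decreases in the authors' deposited table were enzymes of small-molecule metabolism: Cyp2g1 at −7.86 (232-fold, adjusted p = 0.00414), Ces1d at −7.25, Cyp2j8 at −6.39, Cyp2j12 at −6.37, Aadacl2fm1 at −6.36 and Aadacl4 at −5.93. Serpinb6e (−8.60), Atp6v0d2 (−6.65), the metallothionein gene Mt4 (−6.23) and Pla2r1 (−6.01) were the rest in that table.

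Of the 22 stress keratins and alarmins, 14 rose and 0 fell in Bulge (19 and 1 adjusted over the list alone, median 4.94, list test adjusted p = 4.15e-11). Krt16 stood at 6.85 (adjusted p = 0.00149), the connexin 26 gene Gjb2 at 7.69 and Sprr1a at 4.81 in the authors' deposited table. Of 18 cholesterol synthesis genes, 12 rose and 0 fell (18 adjusted over the list alone, median 1.64, adjusted p = 4.15e-11). Sqle rose 5.61-fold (2.49, adjusted p = 0.00531), Cyp51 by 2.24, Fdft1 by 1.94 and Hmgcs1 by 1.67 in the authors' deposited table. Of 7 EGF family ligands, 5 rose, with the same number adjusted over the list alone (median 2.90, adjusted p = 0.000862), among them Epgn at 5.97, Areg at 3.55, Tgfa at 2.99 and Hbegf at 2.90 in the authors' deposited table. The EGF list was not called in EpSCs (list test adjusted p = 0.959) or Germ (0.153). In EpSCs, Btc (4.40) and Tgfa (1.55) were higher and Hbegf (−1.58) and Epgn (−1.29) lower in the authors' deposited table. Of 10 sebaceous gland markers, 6 fell in Bulge (9 adjusted over the list alone, median −3.69, adjusted p = 1.06e-05). Awat1, a wax ester synthase gene, was at −5.35 (adjusted p = 0.0108), Pparg at −4.63 and Far2 at −3.48 in the authors' deposited table.

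Of the 4 neutrophil markers measured, Cxcr2 (4.02), S100a8 and S100a9 rose in Bulge in the authors' deposited table, and 4 rose adjusted over the list alone (median 6.38, adjusted p = 0.00699). S100a8 and S100a9 are also made by inflamed keratinocytes and stand in the stress list too. Immediate early genes were called higher as a list with 0 members called over all genes or adjusted over the list alone (median 0.84, adjusted p = 0.0015). Glycolysis genes had 1 of 17 higher over all genes and adjusted over the list alone, the lactate transporter gene Slc16a3 at 2.44 in the authors' deposited table (list median 0.58, adjusted p = 0.0131, or 0.0746 at a correlation of 0.05 and 0.111 with the fold change as statistic). Hair germ and early anagen genes were lower, with 3 of 15 called and 6 adjusted over the list alone (median −0.65, adjusted p = 0.0483, or 0.14 at a correlation of 0.05). Lef1 (−2.76), Gli1 (−2.60) and Wnt10a (−1.49) fell in the authors' deposited table. Melanocyte markers had 1 of 8 lower, Dct (−2.21 in the authors' deposited table), over all genes and adjusted over the list alone (median −1.13, adjusted p = 0.0483, or 0.111 at a correlation of 0.05). Interferon response genes had 0 higher and 4 lower of 26, over all genes and adjusted over the list alone, and were not called (median −0.07, adjusted p = 0.457). Bulge stem cell markers were not called (2 of 20 lower, 1 higher and 2 lower adjusted over the list alone, adjusted p = 0.457), although Wif1 fell by 3.87 and Cd200 by 1.02 in the authors' deposited table. The Bulge count of called genes was 89 with Benjamini-Yekutieli adjustment and 105 when tested against a fold change of 1.5.

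**Figure D2:**
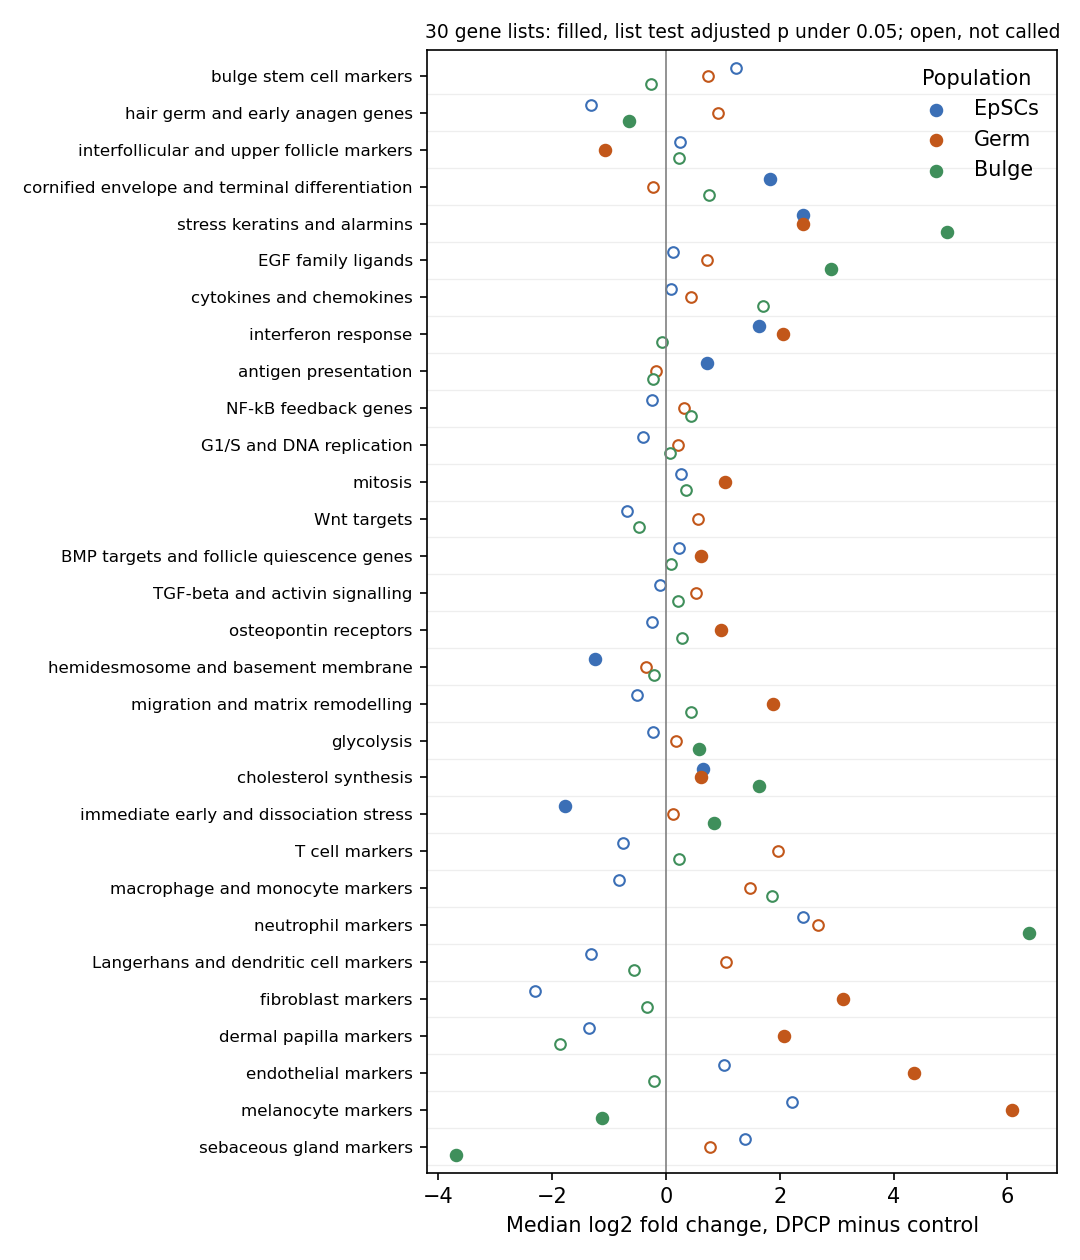
Median log2 fold change, DPCP minus control (horizontal axis), of the measured members of each of 30 gene lists (vertical axis) in EpSCs, Germ and Bulge. Filled points are lists with a list test adjusted p under 0.05, open points are lists not called. Stress keratins and cholesterol synthesis lie to the right in all 3 populations, melanocyte markers reach 6.09 in Germ and sebaceous gland markers −3.69 in Bulge.

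The remaining lists were not called in any population by the list test. Cytokines and chemokines had medians of 0.08 in EpSCs, 0.43 in Germ and 1.71 in Bulge (adjusted p = 0.971, 0.528 and 0.254). Within that list, Ccl2 rose by 1.90 in EpSCs and by 2.20 in Bulge, and Il33 fell by 1.71 and by 2.73, in the authors' deposited table. NF-kB feedback genes had medians of −0.25, 0.32 and 0.44 (adjusted p = 0.33, 0.528 and 0.172) and TGF-beta and activin genes of −0.10, 0.52 and 0.21 (adjusted p = 0.971, 0.0843 and 0.942), in the same order of populations. T cell markers had medians of 1.98 in Germ and 0.24 in Bulge, macrophage markers of 1.47 and 1.86, and Langerhans cell markers of 1.06 and −0.57, with adjusted p from 0.162 to 0.937. With the fold change as statistic, adjusted p was 6.24e-08 for cytokines, 4.92e-07 for macrophage markers and 0.0351 for NF-kB feedback genes in Bulge, 5.6e-08 for macrophage and 0.000418 for T cell markers in Germ, and 0.0378 for Langerhans cell markers in EpSCs, and with ranks or a correlation of 0.05 none of these was under 0.05. Among lists not called, median and test differed in sign for osteopontin receptors in EpSCs, TGF-beta genes in EpSCs and Bulge, cytokines in Germ, and G1/S, BMP, interfollicular and endothelial genes in Bulge. In these lists the mean had the sign of the test, except for osteopontin receptors in EpSCs and cytokines in Germ, where it had that of the median. The mean differed in sign from both median and test for the cornified envelope in Germ (mean 0.33) and T cell markers in Bulge (mean −0.06).

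To ask whether the populations responded alike, the called genes were overlapped. By the calls of the authors' deposited table, a set of 14 genes rose in all 3 populations, against 1.19 expected for independent calls, and 5 fell, against 0.300. The genes higher in all 3 were Adcy7, Arhgef2, Gpx2, Igfl3, Krt6a, Lcn2, Rab31, Sdc3, Serpina3n, Sox13, Spire1, Sulf2, Ugcg and Xdh, and those lower were Ackr4, Cbs, Cib2, Krt1 and Tmod4. Krt6a (chromosome 15, 101689910 to 101694307, GRCm38, ENSMUSG00000058354.7) was 25.2-fold higher in EpSCs, 12.4-fold in Germ and 9.02-fold in Bulge in the authors' deposited table. Gpx2, a glutathione peroxidase, rose by 5.53, 1.77 and 5.57 in that order in the authors' deposited table. Krt1 (chromosome 15, 101845426 to 101850794, ENSMUSG00000046834.7) fell by 1.32, 3.22 and 2.96, and Cbs, the entry enzyme of transsulfuration, by 1.86, 1.93 and 1.33 in the authors' deposited table. EpSCs and Bulge shared 388 higher genes (140.8 expected) and 272 lower genes (142.8 expected), while 89 genes rose in EpSCs and fell in Bulge and 38 did the opposite (141.8 expected for each). Germ and Bulge shared 22 higher (5.996 expected) and 11 lower genes (1.497 expected), and EpSCs and Germ 32 (23.3 expected) and 15 (5.81 expected). In opposite directions, 8 genes rose in Germ and fell in Bulge (6.04 expected) and 0 did the reverse (1.49 expected), while 17 rose in Germ and fell in EpSCs (23.4 expected) and 4 did the reverse (5.77 expected), by the limma calls of the authors' deposited table. Across genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.306 for EpSCs and Bulge, 0.216 for Germ and Bulge and 0.173 for EpSCs and Germ (Spearman's rho 0.324, 0.243 and 0.244). The number shared by all 3 was 0 at an adjusted p under 0.01.

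The size of the DPCP effect differed between populations for named genes and lists. By a test of the difference rebuilt from the authors' deposited table with its limma p-values, 828 genes had unequal effects in Germ and Bulge, 1433 in EpSCs and Bulge and 1690 in EpSCs and Germ. For Germ minus Bulge, the largest differences included Atp6v0d2 (10.81 ± 2.29, rebuilt standard error, adjusted p = 0.00159), Ecscr (9.73 ± 2.10) and Slc14a1 (9.76 ± 2.11) on one side and Slc26a9 (−6.34 ± 1.90) and Krt16 (−5.26 ± 1.61, adjusted p = 0.0279) on the other. The melanocyte gene Dct differed by 8.66 ± 1.54 (adjusted p = 0.000142). EpSCs minus Bulge gave Ear2 at 11.29 ± 2.28, Rgs4 at 10.06 ± 1.66 (adjusted p = 1.19e-06) and Cyp1a1, an aryl hydrocarbon receptor target, at 9.19 ± 2.21, against Greb1 at −9.97 ± 2.09 and Rgs6 at −8.10 ± 1.70. EpSCs minus Germ gave Krt79 at 7.12 ± 1.01 (adjusted p = 2.37e-08) and Defb6 at 6.61 ± 1.32, against Foxp2 at −10.56 ± 2.17 and Cdh2 at −9.98 ± 2.23. The DPCP effect on the interferon response list was higher in EpSCs and in Germ than in Bulge (median differences 1.43 and 2.26, list test adjusted p = 3.83e-05 and 3.32e-07). The rise of stress keratins and alarmins was smaller in EpSCs and Germ than in Bulge (−2.77 and −3.13, adjusted p = 0.00328 and 0.000123). For immediate early genes the DPCP effect was lower in EpSCs than in Bulge (−2.44, adjusted p = 7.62e-11) and Germ (−2.01, adjusted p = 3.47e-07). This test assumes that libraries of different populations are independent.

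**Figure D3:**
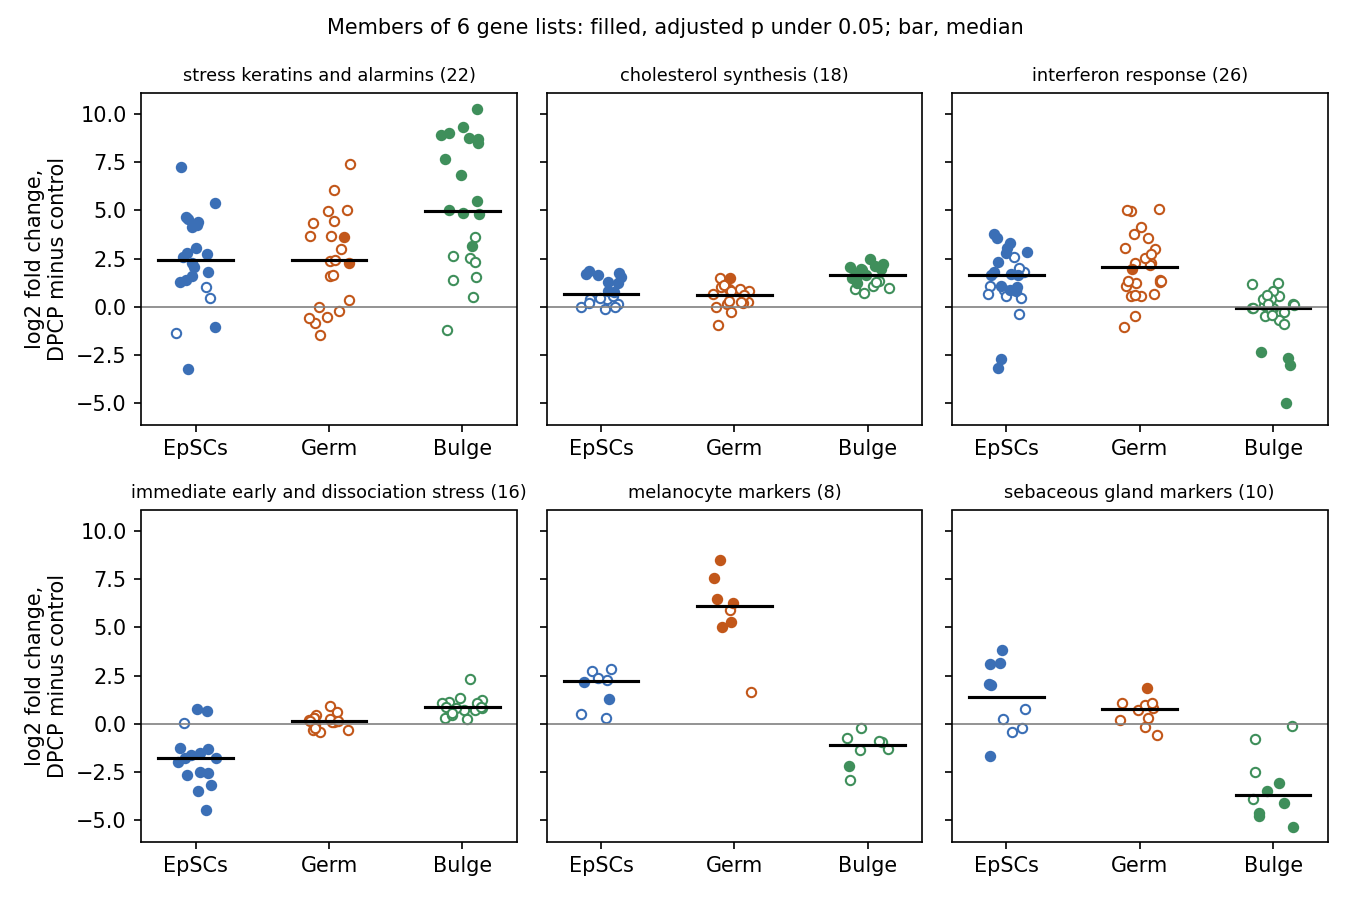
Log2 fold change, DPCP minus control (vertical axis), of each measured member of 6 gene lists in EpSCs, Germ and Bulge (horizontal axis). Filled points have an adjusted p under 0.05 in the authors' deposited table, open points do not, and black bars are medians, which for melanocyte markers are 2.22, 6.09 and −1.13.

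Spp1 (chromosome 5, 104435118 to 104441050, GRCm38, ENSMUSG00000029304.14), which encodes osteopontin, had log2 fold changes of 1.23 in EpSCs, 8.20 in Germ and 6.44 in Bulge in the authors' deposited table. None passed the threshold (adjusted p = 0.359, 0.4 and 0.173). Its receptor gene Cd44 (chromosome 2, 102811141 to 102901665, ENSMUSG00000005087.17) rose 2.65-fold in EpSCs (1.41, adjusted p = 0.000887) and 3.92-fold in Bulge (1.97, adjusted p = 0.0103) in the authors' deposited table. In Germ it stood at 0.46 (adjusted p = 0.241) there, and its effects were not shown to differ between populations (adjusted p of the differences from 0.1 to 0.607). Of 10 osteopontin receptor genes, 3 rose and 0 fell in EpSCs (the same adjusted over the list alone) and 2 rose in Bulge (2 higher and 1 lower adjusted over the list alone). These included Itgav (0.69) in EpSCs and Itga8 (4.17) in Bulge in the authors' deposited table, and neither list was called (adjusted p = 0.976 and 0.461).

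Surface markers commonly used to sort these populations changed in EpSCs. In the authors' deposited table Itga6 fell there by 0.72 (adjusted p = 0.00314), Ly6a, which encodes Sca-1, 2.82-fold (adjusted p = 0.000186) and Cdh3, which encodes P-cadherin, by 0.93 (adjusted p = 0.00601). None of these was called in Germ or Bulge. Ly6a stood at −1.50 in EpSCs, −0.82 in Germ (adjusted p = 0.383) and −2.10 in Bulge (adjusted p = 0.0558) in that table. Itga6 stood at 0.23 in Germ and 0.41 in Bulge, and Cdh3 at 0.91 and −0.12, in the authors' deposited table. Cd34 was not called in any population, at 1.05, 0.73 and −0.54 in EpSCs, Germ and Bulge (adjusted p = 0.273, 0.464 and 0.362) in the authors' deposited table. Krt15 fell by 1.71 in EpSCs and was not called in Germ (adjusted p = 0.0901) or Bulge (−0.30), and Lgr5 rose by 2.02 in EpSCs and stood at 0.74 and 0.35, in the authors' deposited table. Mki67, a proliferation marker, rose by 0.55 in EpSCs (adjusted p = 0.0267) and stood at 1.63 in Germ (adjusted p = 0.0832) and 0.40 in Bulge (adjusted p = 0.582) in the authors' deposited table.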

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

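The tests of the difference between populations, of a lower keratinocyte share, of both explanations of the Germ count and of scaling were chosen only after results were seen, and the tests of transcript length and of further melanocyte genes were written before their outcomes, but after the medians of the lists they explain, were seen.

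The genes and lists given first were picked out because the DPCP effect differed between populations by a test of that difference, which was not run for the Germ count of calls or for the ribosomal and mitochondrial genes. The difference was called for 828 genes between Germ and Bulge (514 above and 314 below), 1433 between EpSCs and Bulge (754 and 679) and 1690 between EpSCs and Germ (796 and 894). Genes called in opposite directions in the authors' deposited table numbered 8, 127 and 21, in the same order.

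The following are median differences of log2 fold changes over the members of lists whose list test of the difference passed an adjusted p of 0.05. For Germ minus Bulge, the positive differences were 7.55 for melanocyte markers, 4.46 for sebaceous gland markers, 4.08 for endothelial markers, 3.59 for fibroblast markers, 2.99 for dermal papilla markers and 2.26 for the interferon response. Smaller positive differences were 1.25 for hair germ and early anagen genes, 0.78 for BMP targets and quiescence genes, 0.62 for mitosis, 0.47 for Wnt targets and 0.46 for bulge stem cell markers. The negative ones were −3.13 for stress keratins and alarmins, −1.96 for EGF ligands, −0.98 for cholesterol synthesis, −0.77 for interfollicular markers, −0.75 for the cornified envelope, −0.63 for immediate early genes and −0.46 for glycolysis.

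For EpSCs minus Bulge, the differences were 4.10 for sebaceous gland markers, 3.24 for melanocyte markers, 1.53 for interfollicular markers, 1.43 for the interferon response, 1.34 for bulge stem cell markers and 0.87 for antigen presentation. They were −5.88 for neutrophil markers, −2.77 for stress keratins and alarmins, −2.44 for immediate early genes, −1.45 for EGF ligands, −0.94 for NF-kB feedback genes, −0.94 for hemidesmosome genes (−0.935 unrounded), −0.83 for migration genes, −0.74 for cholesterol synthesis and −0.66 for glycolysis.

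For EpSCs minus Germ, the differences were 1.74 for interfollicular markers, 0.98 for the cornified envelope and 0.77 for antigen presentation. They were −4.43 for melanocyte markers, −3.72 for fibroblast markers, −2.54 for migration genes, −2.01 for immediate early genes, −1.32 for Wnt targets, −1.30 for hair germ genes, −0.95 for hemidesmosome genes, −0.78 for mitosis and −0.52 for G1/S genes.

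Melanocyte markers were higher in DPCP Germ. A lower share of keratinocytes would raise markers of other cell types alike only if keratinocytes expressed all of them equally little, and levels were not used here. The melanocyte median exceeded by 3.837 that of 41 T cell, macrophage, Langerhans, fibroblast, dermal papilla and endothelial markers (6.09 against 2.25, permutation p = 8e-05). The melanocyte list had been chosen for its high median. Over all 9 lists of other cell types, neutrophil and sebaceous ones included, a permutation test that allows for the choice of the list furthest from the rest gave p = 0.0075. The melanocyte list thus rose more than the others, but this cannot decide whether a lower share was the whole cause. Both permutation tests treat genes as independent, and a lower share stays open. Endothelial (4.37), fibroblast (3.12) and dermal papilla markers (2.08) were called higher too. Keratinocyte identity genes were lower (median −0.48, list test adjusted p = 0.0362, or 0.0901 at a correlation of 0.05). A trend with transcript length is argued against by 0% of 10000 length-matched random lists reaching the melanocyte median. More melanocyte-lineage RNA in the DPCP Germ libraries is a candidate explanation, since melanocyte genes outside the list were higher as a set (limma list test adjusted p = 0.0362 over the 7 later lists, 0.0301 before adjustment, but adjusted p = 0.0701 with ranks and 0.0796 at a correlation of 0.05). Their Germ median was 1.26, below that of the fixed list (6.09) and of the 41 other markers (2.25). Of these 9 further genes, 1 was called over all genes, and 5 rose and 1 fell adjusted over the list alone. Carry-over of melanocytes in the sort was not separated from a change in melanocyte cells of the germ, and whether all 3 DPCP libraries share the rise is not analysed here.

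Germ had few called genes for the size of its fold changes. Fewer changed genes in Germ is argued against as the whole cause, because the number of genes at an unadjusted p under 0.05 was 0.878 of that in Bulge while the ratio of called genes was 0.103. At an adjusted p under 0.10 the Germ count rose 6.322 times and the Bulge count 1.89 times, which describes where the Germ p-values lay and names no cause. The median standard error rebuilt from the authors' deposited table was 0.392 in Germ, 0.367 in Bulge and 0.287 in EpSCs, and what set that spread was not tested.

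Ribosomal protein genes and mitochondrially encoded genes were lower in EpSCs, with medians of −1.27 and −2.55 over 82 and 12 genes, and in Germ as well (−1.98 and −2.42, adjusted p = 2.04e-28 and 7.28e-06). A trend with transcript length is argued against as the whole cause by 0% of 10000 length-matched random lists reaching either median, in EpSCs or in Germ. The median over all genes, −0.0034, says nothing about a single scaling factor for all genes, since normalization ordinarily holds it near 0, so the fall is one relative to other genes. A difference in cell state or RNA quality could also lower these genes, and it was not tested because values per library were not used.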

How the results depend on the processing

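All alternatives reported here were chosen after seeing the data, because those listed beforehand needed values per library: other normalizations, filters, pseudocounts and models, fits of the contrast's groups alone, a replicate block, leaving out each replicate, and an estimated inter-gene correlation were not run, and the comparisons between populations in control skin were not made. A test against a fold change of 1.5 had been listed as a limma refit and was rebuilt from p-values instead. No paired analysis was possible because the columns used are comparisons that carry no replicate number. Other splits of the samples could not be drawn for the same reason, so whether a random division of the samples or a single library could give as many calls is open. Depth is unknown, and the log2 fold change correlated with transcript length across genes (Spearman's rho 0.125 in EpSCs, 0.266 in Germ and 0.218 in Bulge).

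The counts of called genes in the authors' deposited table (5516 in EpSCs, 146 in Germ, 1421 in Bulge and 19 in all 3 in the same direction) cannot rise under a stricter setting. With Benjamini-Yekutieli adjustment they were 2590, 0, 89 and 0. At an adjusted p under 0.01 they were 3313, 14, 212 and 0. Tested against a fold change of 1.5 they were 1161, 9, 105 and 0. Requiring a log2 fold change of at least 1 left 3073 in EpSCs, 146 in Germ and 1290 in Bulge. With p adjusted over protein-coding genes alone they were 5404, 149 and 1394. The share of calls that were higher was 49.8% in Bulge, and 34.8% with Benjamini-Yekutieli adjustment, 36.8% at an adjusted p under 0.01 and 29.5% against a fold change of 1.5. In EpSCs it was 49.8%, and 43.1% with the minimum size. In Germ it was 80.1%, with 13 of 14 higher at an adjusted p under 0.01 and 9 of 9 against a fold change of 1.5. Of 301 named genes, 54 lost their call in EpSCs, 37 in Germ and 88 in Bulge under Benjamini-Yekutieli adjustment, and none changed side when p was adjusted over protein-coding genes alone. The 301 include genes that were not called in a given population, so these losses are not shares of 301 calls. In Germ no gene kept its call under Benjamini-Yekutieli adjustment, so the 37 were all of the named Germ calls.

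Genes with unequal effects at an adjusted p under 0.01 numbered 210 for Germ against Bulge, 536 for EpSCs against Bulge and 819 for EpSCs against Germ. With 4 degrees of freedom in place of normal scores they numbered 1272, 1926 and 1809. In simulated data that setting gave 73 calls with 10 false, 101 with 20 false and 77 with 11 false. The false share was larger than with normal scores in each comparison. It need not hold for the real data, which gave many more calls.

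Of 30 lists, 7 were called in EpSCs, 12 in Germ and 9 in Bulge. With the log2 fold change as the statistic the EpSCs count was 14, the Germ count 13 and the Bulge count 14. That statistic weighs large fold changes of uncertain genes as much as those of certain ones. The lists called only with that statistic were bulge stem cell, interfollicular, Langerhans, fibroblast, endothelial, melanocyte and sebaceous gland markers in EpSCs, T cell, macrophage and neutrophil markers in Germ, and the cornified envelope, cytokines, NF-kB, migration, macrophage and dermal papilla lists in Bulge, while BMP targets and cholesterol synthesis in Germ and glycolysis in Bulge lost their calls. At a correlation of 0.05 the calls of the cornified envelope in EpSCs, BMP targets in Germ and hair germ genes, glycolysis and melanocyte markers in Bulge were lost. In Germ the stress keratin, osteopontin receptor, migration, cholesterol synthesis, fibroblast and dermal papilla lists then stood just under the threshold (list test adjusted p = 0.0495 for each). With ranks the calls of the cornified envelope in EpSCs and dermal papilla markers in Germ were lost. No called list changed direction under any setting run.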

Other observations

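The lists of this part were added after seeing the data, except that nuclear-encoded oxidative phosphorylation genes and further melanocyte genes were listed before their values were seen. Adjusted p here is over the 7 later lists. For lists added after seeing the data, the list test used the same values, so its p-value is no independent support. Klk6 and Cyp2g1, among the largest changes in Bulge, are members of such lists.

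Genes of protein synthesis and respiration moved in EpSCs and Germ. Of 82 cytosolic ribosomal protein genes, 76 fell in EpSCs in the authors' deposited table (median −1.27, list test adjusted p = 6.26e-23). In Germ 0 were called over all genes and 77 fell adjusted over the list alone (median −1.98, adjusted p = 2.04e-28), while Bulge had a median of −0.24 (adjusted p = 0.0988). Rps6 stood at −1.19 in EpSCs (adjusted p = 0.00304) and −1.35 in Germ (adjusted p = 0.138) in the authors' deposited table. Of 12 mitochondrially encoded protein genes, 10 fell in EpSCs (median −2.55, adjusted p = 4.04e-06), and Germ had 0 called and 5 lower adjusted over the list alone (median −2.42, adjusted p = 7.28e-06). The Bulge median was −0.60 (adjusted p = 0.0988). Of 77 nuclear genes for oxidative phosphorylation, 33 fell and 5 rose in EpSCs (median −0.42, list test adjusted p = 6.18e-05, or 0.203 with the fold change as statistic). That median was reached by 17.7% of length-matched random lists, against 0% for the Germ median and 78.1% for the Bulge median. In Germ 0 of them were called over all genes or adjusted over the list alone (median −1.01, adjusted p = 1.71e-15), and in Bulge 2 fell (median −0.20, adjusted p = 0.0988).

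Kallikreins, serine proteases of the outer epidermis, rose in Bulge. Of 9 measured genes 6 rose and 0 fell (7 adjusted over the list alone, median 3.98, adjusted p = 5.87e-07), and Klk13 stood at 8.11, Klk10 at 6.58 and Klk8 at 3.98 in the authors' deposited table. EpSCs had 5 higher and 1 lower (median 0.98, adjusted p = 0.0668) and Germ 0 called (median 0.62, adjusted p = 0.0539). Of 15 keratinocyte identity genes, 4 rose in Bulge (median 0.58, adjusted p = 0.0159, or 0.0623 at a correlation of 0.05), 4 rose and 7 fell in EpSCs (median −0.36, adjusted p = 0.448) and 0 were called in Germ (median −0.48, adjusted p = 0.0362, or 0.0901 at a correlation of 0.05). Krt5 fell by 1.89 in EpSCs in the authors' deposited table. Further melanocyte genes had medians of −0.33 in EpSCs, 1.26 in Germ and 0.24 in Bulge (list test adjusted p = 0.895, 0.0362 and 0.374).

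Families of xenobiotic metabolism (glutathione transferases, cytochromes P450, carboxylesterases and related enzymes) were lower in Bulge, with 26 of 65 genes lower and 3 higher (median −1.16, adjusted p = 6.59e-08). In Germ 7 fell (median −0.41, adjusted p = 0.00133, or 0.0615 at a correlation of 0.05), and in EpSCs 18 rose and 13 fell (median −0.15, adjusted p = 0.483). A trend with transcript length was tested as the cause in Bulge, and 0% of 10000 length-matched random lists had as low a median. Sebaceous gland markers fell in Bulge as well (median −3.69, adjusted p = 1.06e-05 over the 30 lists), so fewer sebaceous cells in the sort may be part of it. Interfollicular and upper follicle markers went both ways as a list (median 0.23, adjusted p = 0.942). Over all genes 2 of the 14 rose and 4 fell (5 and 5 adjusted over the list alone). Mt4 (−6.23), Krt1 (−2.96) and Krt10 (−2.55) were lower in the authors' deposited table. Ly6a (−2.10), Krtdap (1.74) and Sbsn (1.14) were not called there. Among the list's genes of the upper follicle, Cst6 (2.57) and Plet1 (1.24) were higher, Defb6 (1.62), Krt79 (1.17) and Lrig1 (0.50) were positive but not called, and Lgr6 (−4.10) was lower in the authors' deposited table. The called ones among these went both ways, so they do not decide whether upper follicle cells were lost. These genes were picked after their values were seen and not tested as a set, and a change within bulge cells was not tested.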
